A study of Mus musculus with 24 samples.

How the data were processed

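Placental RNA of 24 libraries was sequenced as single-end, poly(A)-selected messenger RNA libraries, per the labels' protocols. Libraries were grouped from their titles into 8 groups of 3 by fetal sex, maternal diet and genotype. The submitters' processing notes name Bowtie2, the mouse build mm9, R 4.05 and limma, without a role or order for each. The read counter, the annotation and the rule by which genes were kept are not given in the sources used here.

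The authors deposited 1 table of raw read counts per gene for the whole series. Its 24 value columns carry running numbers that match no title, description or other label of a library. Assignment by column order or by the values themselves was not used. The first is an assumption, and the second would make a comparison circular for the genes used in the assignment. These columns were examined to establish their unit, which included viewing the column totals and a few rows, among them values of 0 for Y-linked genes in the first column. No column was assigned from what was seen. They were left out of every result, and no normalisation, differential expression test, set test or depth from them is used or reported. All 15 comparisons of diet, genotype and sex planned before the data were examined, the planned test of Myd88 and the planned gene list tests were therefore not run.

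The columns of Ensembl gene identifiers and gene symbols were read with Python 3.11.15. Identifiers were matched without version to GENCODE M21, an annotation of GRCm38. Because the notes name another build, it was used for gene names and classes only and no coordinates are given. The 37 gene lists were fixed before the data were examined. A member counted as present if any of its listed spellings was a symbol in the table or its current symbol led to an identifier there. A member kept under another older symbol and an identifier outside GENCODE M21 would have been counted as having no row. In the erythroid list, Hbb-bs and Hbb-bt were merged with Hbb-b1 and Hbb-b2, since each pair of names led to 1 identifier. The lists given as name patterns were expanded over the protein-coding symbols of GENCODE M21. The rule fixed for naming genes rests on test results and could not be applied, so the genes named here were chosen after seeing which had a row.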

Results

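The study measured messenger RNA by sequencing in mouse placenta collected at 17.5 days post coitum, close to term. Dams came from a conditional knockout line for Myd88, the adaptor protein through which most Toll-like receptors and the interleukin-1 receptor signal, and were fed a control or a high-fat diet. Placental RNA was pooled within sex and genotype. The number of placentas and litters behind each library is not stated here, so the independence of libraries within a group cannot be judged. Whether genotype refers to the dam or to the placenta is not stated here either. The labels describe 24 libraries in 8 groups of 3, one group for each combination of fetal sex, maternal diet and genotype (conditional knockout or floxed). The design addresses whether the placental response to a maternal high-fat diet depends on Myd88 and on fetal sex.

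No expression difference between diets, genotypes or sexes is reported. The table of read counts names its 24 value columns only by a running number that matches no label of any library, so no column was assigned to a group. The expression values, the depth per library and the level of Myd88 were left out and not analysed here. What follows describes only which genes have a row in the table, taken from its columns of gene identifiers and symbols. A row shows that a gene was kept in the table, and gives neither its level nor its direction of change. A missing row does not show that a gene was not expressed. The rule by which genes were kept is not given in the sources used here.

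The table held 14531 genes, each with its own identifier and symbol. Of these, 14193 identifiers (97.7%) had an entry in the mouse annotation GENCODE M21, and 338 had none. Protein-coding genes made up 13670 of the matched rows, which is 62.3% of the 21951 protein-coding genes in that annotation. The largest non-coding classes were antisense transcripts with 153 rows, processed transcripts with 139 rows and long intergenic non-coding RNAs with 95 rows.

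Genes of the Toll-like receptor and Myd88 pathway had rows for 36 of 41 listed members. Myd88 itself was among them, as were Tlr4, the receptor for bacterial lipopolysaccharide, Tlr2, Irak1, Irak4 and Traf6. Tlr1, Tlr8, Tlr9, Ticam2 and Il1rl1 had no row. Inflammatory cytokines and NF-kB targets were covered for 24 of 34 members. Tnf, Il1b and Ccl2 had rows, whereas Il6, Il10, Cxcl2, Ccl3, Ccl4 and Ccl5 had none. Interferon-stimulated genes were covered for 35 of 36 members, with Psmb9 as the exception.

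Trophoblast genes were well covered. All 17 syncytiotrophoblast markers had rows, including Gcm1, a transcription factor of labyrinth development, and the fusogens Syna and Synb. The rows of Syna and Synb carried the symbols Gm52 and D930020E02Rik and were found through their identifiers. All 30 spongiotrophoblast and glycogen cell markers had rows, including Tpbpa and Pcdh12. Trophoblast giant cell markers were covered for 20 of 24 members, without Prl3d2, Prl3d3, Cts7 and Cts8. The placental prolactin family was covered for 23 of 25 members. Several members of the prolactin, cathepsin and pregnancy-specific glycoprotein families are near-identical copies, so that reads may be shared between them.

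Markers of the other cell types that placental tissue can hold were covered unevenly. All 22 endothelial markers, all 22 pericyte and fibroblast markers and all 25 decidual and uterine markers had rows. Macrophage markers were covered for 21 of 22 members, without Cd163, and yolk sac endoderm markers for 28 of 30. Erythroid markers were covered for 19 of 24 members, without Hbb-bh1, Ahsp, Klf1, Hemgn and Rhag. Neutrophil markers had rows for 9 of 15 members. Markers of NK and T cells had rows for 10 of 27 members, and the T cell receptor complex genes Cd3e, Cd3d and Cd3g were among those without one.

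Nutrient-handling genes had rows for most members. Amino acid transporters were covered for 28 of 29 members and glucose transporters for 11 of 13. Fatty acid uptake and storage genes were covered for 28 of 38 members. The hepatic binding protein Fabp1, the intestinal binding protein Fabp2 and the lipid droplet protein Plin1 were among those with no row. Fatty acid oxidation genes and PPAR targets were covered for 30 of 33 members, without Ppara, Cyp4a10 and Cyp4a14. Cholesterol synthesis and uptake genes were covered for 25 of 28 members, without Hmgcs1, Idi1 and Pcsk9. All 17 fatty acid synthesis genes, all 27 genes of the unfolded protein response and all 34 genes of IGF and insulin signalling had rows. Imprinted genes were covered for 40 of 44 members.

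Among sex-linked genes, the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty had rows and Usp9y, Zfy1, Zfy2 and Sry had none. All 10 genes listed for X inactivation and escape had rows, including Xist.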

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

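The other scalings, count filters, tools, designs and left-out libraries set before the data were examined all concern tests on the read counts and were not run, since no column was assigned to a group. No paired analysis was possible because the numbered columns carry neither a group nor a replicate number. The titles give a replicate number within each group but name no litter or dam that would pair libraries across groups. Both alternatives tried were chosen after seeing the data. Of the table's symbols, 13093 equalled a symbol in GENCODE M21, against 14193 identifiers found there. The symbol count did not require the symbol to belong to the same gene. Among the rows found by identifier, 1373 carried a symbol that differed from that of GENCODE M21. With the first spelling of each list member only, 30 of the 37 list counts did not change and 7 fell, by at most 2 members.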

Other observations

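Some gene groups not described above also had uneven coverage. None of the 13 mitochondrially encoded protein genes had a row, while nuclear-encoded genes of oxidative phosphorylation had rows for 74 of 81 members. Cytosolic ribosomal protein genes were covered for 72 of 80 members, without Rpl38, Rpl41, Rps7, Rps23, Rps27 and Rps29, as well as the paralogs Rpl3l and Rpl10l. Cell cycle genes were covered for 34 of 36 members, without Bub1 and Aurkb, and steroid synthesis genes for 15 of 18, without Cyp19a1, Hsd17b1 and Srd5a2. Hypoxia and glycolysis genes had rows for 31 of 32 members, without Car9. Oxidative stress genes and NRF2 targets were covered for 25 of 27 members, without Gsta1 and Gsta2. All 29 angiogenic factors and all 19 circadian clock genes had rows. Immediate early and dissection stress genes were covered for 25 of 27 members, and pregnancy-specific glycoproteins and Ceacams for 25 of 28. No explanation for these gaps was tested, and a missing row does not show that a gene was not expressed.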
